A study of Mus musculus and Homo sapiens with 7 samples.

How the data were processed

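The study joined a pooled CRISPR/Cas9 screen in mouse cells with an RNA immunoprecipitation of the protein EOLA1 in human cells. The screen used B16-F10 cells, a mouse melanoma line, that carried Cas9 and a library of guide RNAs and were selected with puromycin at 2 µg/mL for 7 days. The cells were then kept for 48 h in medium with glucose or with galactose. Cells forced to use galactose gain little ATP from glycolysis and lean on mitochondrial respiration. Genomic DNA of living cells from glucose medium (2 libraries) and of dead cells from galactose medium (3 libraries) was collected, and guides were amplified from 5 µg of it. Medium and cell state therefore changed together, and no comparison here separates them. For the UV-RIP (immunoprecipitation of RNA crosslinked to a protein by ultraviolet light), HEK293T cells, a human embryonic kidney line, were irradiated at 400 mJ/cm2 and lysates were precipitated with an antibody to EOLA1, in 2 replicates.

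Per the submitters' processing notes, the tools were MAGeCK 0.5.9.5, Trim Galore, STAR and Picard (no version given for the last 3), with the builds GRCm39 and GRCh38.p14. The role of each tool, the guide counter and its settings are not given in the sources used here. Per the file headers, the authors' deposited guide table holds, for each of 10021 guides, normalised guide counts of the 2 living and 3 dead libraries. They stand together in one cell per group, so the libraries are called a and b, or a, b and c, by their place in the cell, which carries no replicate number. The deposited signal columns give one normalised count per group, and for the dead cells this was the median of the 3 libraries in all 10021 rows. The authors' log2 fold change, p-value and FDR per guide come from the same table. The authors' deposited gene table lists 925 entries (1 of them the non-targeting guides) with a robust rank aggregation score, a p-value and an FDR for each direction, and a log2 fold change. The authors' UV-RIP tables hold whole-number counts in 332 bins of the mitochondrial chromosome, each of 50 bases except the last of 19. What was counted (reads, fragments or bases), and whether strands were kept apart, are not given in the sources used here.

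In each screen library the low values were whole multiples of 1 step, the value of a single read (100% of them within 0.1 read). Division by that step recovered whole reads. The recovered totals were 6801049 and 8492138 reads in living libraries a and b, and 14722850, 13275792 and 15591466 in dead libraries a, b and c. A single read was worth 1.57 and 1.25 normalised counts in the living libraries and 0.761, 0.863 and 0.774 in the dead ones. The median guide had 149 and 189 reads in the living libraries and 273, 275 and 285 in the dead ones. The UV-RIP counts summed to 114188 and 217229 in replicates 1 and 2. Reads carry no molecular identifiers, so intervals on counts cover counting error only.

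For the screen, log2(normalised count + 1) was taken for the guides with a mean of at least 10 over the 5 libraries. These values were averaged per gene and library for the 915 genes with at least 3 such guides (6684 guides). As 3 of the 5 libraries were dead ones, the filter more readily kept rare guides that were higher in dead cells. Dead galactose libraries were then compared with living glucose libraries in limma (lmFit and eBayes, 2-sided, Benjamini-Hochberg, threshold 0.05). Changes on this scale understate those of guides with low counts. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Guides of 1 gene were compared by an exact 2-sided binomial test against 43.7%, the share of all tested guides that were higher in dead cells. Before the data were examined, 27 lists of mitochondrial, metabolic and cell death genes were fixed. So was the rule for the genes named: Eola1, the 10 highest and 5 lowest genes of the limma fit that passed with every dead library on one side of both living ones (filled up by the smallest p where fewer did), the top 10 genes for gain and top 5 for loss in the authors' deposited table, and up to 3 members of each list that passed camera or, if none did, of the 3 lists with the smallest camera p. The last clause could not be applied, as camera was not run on these lists. Of the genes this rule gave, 1 is not reported here, though it is included in counts over genes. For the UV-RIP it took the mitochondrial rRNAs, the mitochondrial mRNAs and the 10 highest other RNAs. A list of nuclear RNAs fixed with them was not used, since the tables analysed hold the mitochondrial chromosome. A further 9 lists were compiled after the gene names and the leading genes of the fit had been seen, and tested with camera (preset correlation 0.01) and with fry. The guide table listed Eola1 under an older symbol, which the reference table for the assembly GRCm38.p6 pairs with Eola1. That table was used for names only, since its build differs from the authors', and no mouse coordinates are given.

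The UV-RIP tables have a single group and no input or control column, so no test between groups was made. Each bin was assigned by its midpoint to a gene of the standard map of the human mitochondrial genome. The map's 37 genes had the same class and order as the 37 mitochondrial genes of the mouse reference table, with lengths differing by at most 23 bases. Intervals of shares are 95% Wilson intervals. Positions are 1-based on the mitochondrial chromosome of GRCh38.p14, whose last base is 16569.

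Alternatives were other pseudocounts, guide filters, a median in place of the mean of guides, rescaling to equal totals, centring on non-targeting guides, a trended prior, leaving out each library, and robust rank aggregation of guide p-values. edgeR's quasi-likelihood test on recovered reads was added after the data had been seen. The screen tests were checked on simulated guide counts drawn from the living libraries' means, with the guides' own dispersions and 200 changed genes, in 5 runs of about 913 genes. For dead against living cells, limma recovered 97.9% of genes changed by 2 log2 units, 58.7% of those changed by 1 and 10.6% of those changed by 0.5, and called 0.644% of unchanged genes. Robust rank aggregation recovered 98.2%, 73.4% and 10.6%, and called 0.028% of unchanged genes. edgeR recovered 100%, 98.5% and 67.9%, and called 1.15% of unchanged genes. The dispersions had been estimated by edgeR, so the setting may favour edgeR. The simulation gave each library its own independent spread and made all guides of a gene act alike. The intraclass correlation of guide changes was taken after the mean change of guides of like abundance had been removed. Tested on 915 simulated genes whose guides shared 1 effect, it gave 0.0063, 0.0994 and 0.3275 for true values of 0, 0.1 and 0.3. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.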

Results

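The series addressed EOLA1, a protein that its title places in mitochondria and ties to mitochondrial translation. A guide library in mouse B16-F10 melanoma cells was sequenced from living cells in glucose medium (2 libraries) and from dead cells in galactose medium (3 libraries). RNA crosslinked to EOLA1 was sequenced from human HEK293T cells in 2 replicates. The living libraries held 6801049 and 8492138 reads and the dead ones 13275792 to 15591466, so each value rests on more reads in the dead cells. The library held 9271 guides against genes, 375 non-targeting guides that match no site and 375 safe-targeting guides aimed at sites outside genes. Of all guides, 2247 (22.4%) were at 0 in all 5 libraries.

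Guides against Eola1 were compared first, as the gene the study is about: guides that mark a gene needed in galactose would be more frequent among dead cells. Eola1 guides were 0.28 ± 0.21 log2 units higher in dead galactose cells than in living glucose cells (SE, 3 against 2 libraries), a fold of 1.21. The 95% interval of the fold ran from 0.846 to 1.74, so the difference did not exceed the spread between libraries (limma, adjusted p = 0.674 over 915 genes). The mean log2 guide count was 9.68 and 9.69 in the living libraries and 9.87, 9.81 and 10.22 in the dead ones, all 3 above both living values. Without dead library c the Eola1 value was 0.154. By size of the change, Eola1 ranked 88 among the 915 genes. Relative to the median gene, which lay at −0.16, Eola1 was 0.435 higher. That difference was 0.35 with guides of a mean of at least 50, and −0.024 with no guide filter.

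Of the 10 Eola1 guides in the library, 4 were at 0 in all libraries and 1 was under the filter, with a mean of 6.84. The most abundant of the 5 tested guides had 7772 ± 392 normalised counts in living cells (SD, n = 2) and 9118 ± 2061 in dead cells (SD, n = 3). The next had 1469 ± 3.32 and 2084.5 ± 384 normalised counts, and the one after it 1243 ± 48.7 and 1664 ± 580. A further Eola1 guide had 366 ± 53.0 normalised counts in living and 578 ± 29.1 in dead cells. The rarest tested guide went the other way, from 72.7 ± 11.9 to 61.1 ± 23.3. With 4 of 5 guides higher, the exact binomial test gave p = 0.175. In the authors' deposited table Eola1 was placed 30 for gain among dead cells, with a log2 fold change of 0.356, a p-value of 0.0456 and an FDR of 1. Without a filter on rare guides the value for Eola1 turned to −0.17, as the guide left out otherwise had 32.9 and 1.25 normalised counts in the living libraries and 0 in all dead ones. Its mean in living cells was 17.1. A Nat9 guide with the reverse pattern, 0 in living cells and a mean of 17.2 in dead ones, passed the filter. The sign of the Eola1 value thus depends on a filter that more readily keeps rare guides higher in dead cells.

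**Figure D1:**
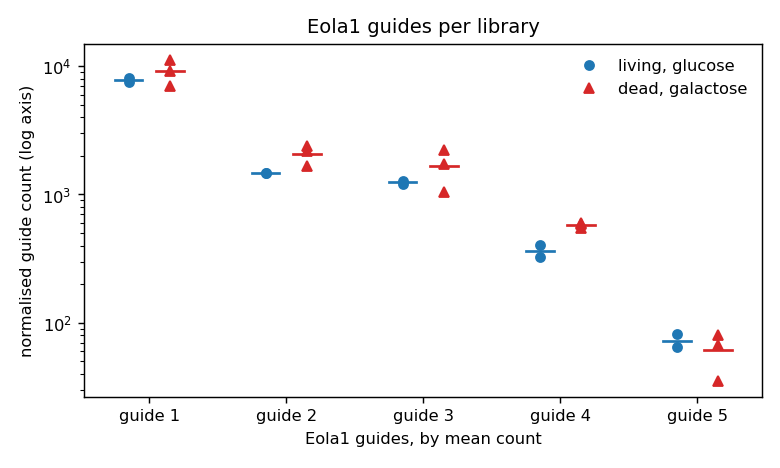
Normalised counts (log axis) of the 5 tested Eola1 guides in the 2 living glucose libraries (circles) and the 3 dead galactose libraries (triangles), with group means as bars. The mean is higher in dead cells for 4 guides and lower for the rarest, where it is 61.1 against 72.7.

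Across the other genes the question was which knockouts were more or less frequent among the dead cells. Zfp931 and Zfp865, both zinc finger genes, were among the genes with the highest guides, and the neuropeptide gene Nmb was among those with lower guides. Zfp931 guides were 1.26 ± 0.24 log2 units higher in dead cells (SE, limma adjusted p = 0.236), with 3 of 3 guides higher, the most abundant of them by 2.09 and the others by 0.96 and 0.74. Nmb guides were lower by a log2 change of −1.05 ± 0.19 (adjusted p = 0.236), with 2 of 9 guides higher. By edgeR on reads summed per gene, which gives abundant guides more weight, Zfp931 stood at 1.81, Zfp865 at 0.58 and Nmb at −0.33. None of these passed.

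At an adjusted p of 0.05, limma called 0 genes higher and 0 genes lower of the 915 tested, with a smallest adjusted p of 0.236. At an unadjusted p under 0.05 it found 14 genes higher and 73 lower, where 22.9 in each direction would be expected of independent libraries. These counts moved to 43 and 103 without dead library a, 6 and 26 without living library a, 4 and 28 without living library b, 39 and 50 with the median of guides, 10 and 127 at equal totals, and 22 and 43 with guides of a mean of at least 50. Robust rank aggregation also called 0 and 0 (56 higher and 49 lower at an unadjusted p under 0.05), as did edgeR on recovered reads (107 and 68), where Zfp316 came closest (0.77, adjusted p = 0.0549). All 3 dead libraries lay above both living ones for 76 genes and below both for 219, where 91.5 in each direction would be expected of independent libraries. In all, 291 genes had higher and 624 had lower guides (68.2% lower), with a median of −0.16. Scaled to equal totals the median gene was at −0.28 and 79.8% of genes were lower, and with the median in place of the mean of guides 57.2% were lower.

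The genes with the smallest p among those with higher guides also included Zfp865, at 1.05 ± 0.37 with 5 of 6 guides higher. Dfnb59, which encodes the hearing protein pejvakin, stood at 0.68 ± 0.20 with 7 of 8 guides higher (0.38 by edgeR). Fam78a stood at 0.65 ± 0.19 with 5 of 6 guides higher (0.26 with the median guide and 0.29 by edgeR). For 4930564B18Rik (0.93 ± 0.19), Nat9 (0.77 ± 0.20), Atxn7l3b (0.64 ± 0.22) and the meiosis gene Hormad1 (0.62 ± 0.22), the value was below 0 when the median guide was taken in each library in place of the mean (−0.0419, −0.53, −0.00737 and −0.26). Tbc1d14, a regulator of autophagy, stood at 0.71 ± 0.20 through 1 rare guide that was higher by 5.08, at 0.0881 with guides of a mean of at least 50 and at −0.0871 by edgeR. For 4930564B18Rik the mean rested on 1 guide at 0 in both living libraries and at 78.4, 191 and 111 normalised counts in the dead ones. On the lower side, Lrwd1, a partner of the origin recognition complex, stood at −1.76 ± 0.27 with 1 of 6 guides higher, and Sspo, a gene for a secreted brain protein, at −1.68 ± 0.31. The G protein regulator Rgs10 stood at −1.17 ± 0.21 and Sec61a1, the channel that moves proteins into the endoplasmic reticulum, at −1.23 ± 0.22. All of these were nearer 0 without rare guides: with guides of a mean of at least 50 they were −0.91 for Lrwd1, −0.76 for Sspo, −0.48 for Rgs10 and −0.28 for Sec61a1. By edgeR Rgs10 was higher, at 0.40, as was Lrwd1 at 0.0792, while Sspo stood at −0.38 and Sec61a1 at −0.0961. The most abundant Rgs10 guide was higher by 0.71. The adjusted p of these genes lay between 0.236 and 0.398.

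**Figure D2:**
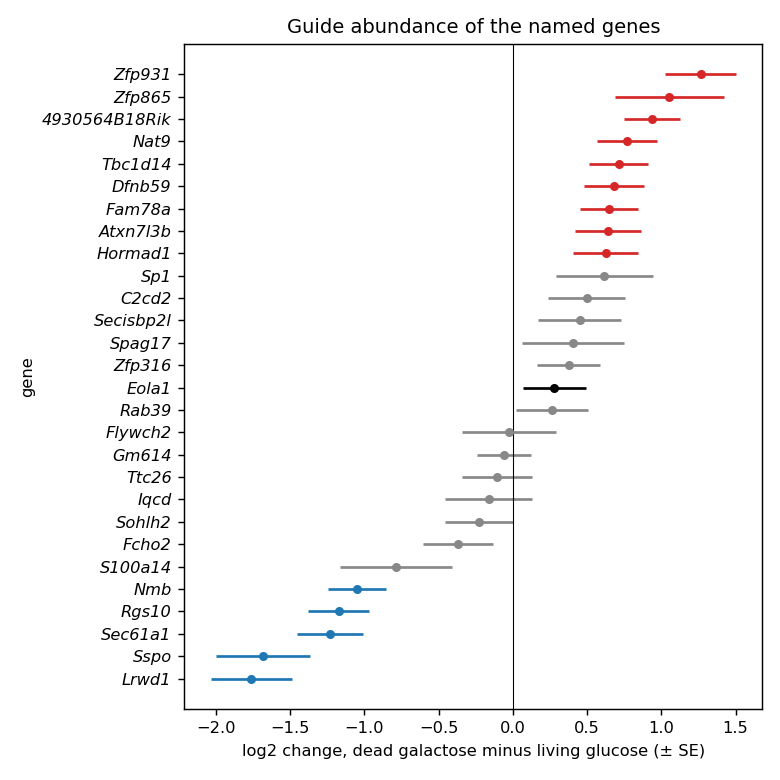
Log2 change of guide counts per gene, dead galactose minus living glucose, with the SE of the limma fit as bars, for Eola1 (black), the named genes with small p in each direction (red, higher; blue, lower) and named genes from the authors' table (grey). Values run from −1.76 for Lrwd1 to 1.26 for Zfp931, Eola1 lies at 0.28, and no gene passed an adjusted p of 0.05.

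The authors' deposited gene table called 0 genes for gain and 0 for loss at an FDR of 0.05. Its FDR for gain was 1 for every entry, and 31 entries had a p-value under 0.05. Its first gene for gain was Sp1, a general transcription factor, with a p-value of 0.00615. Iqcd, Ttc26 (a cilium transport gene) and Rab39 (a small GTPase) came next. In the limma fit Sp1 stood at 0.62 ± 0.33 with 7 of 8 guides higher (−0.0717 by edgeR), and Rab39 at 0.26 ± 0.24 with 7 of 9 (0.69 by edgeR). The rarest tested Sp1 guide stood at 3.67, the most abundant at −0.50 and the others between 0.15 and 0.67. Secisbp2l stood at 0.45 ± 0.28 with 7 of 9 guides higher (0.54 by edgeR), Zfp316 at 0.37 ± 0.21 with 7 of 9 and C2cd2 at 0.50 ± 0.26 with 5 of 10. Without its rare guide, which was higher by 3.93, C2cd2 was at 0.12. Others of that table's leading genes for gain had values under 0 by limma: Iqcd (−0.16 ± 0.29), Ttc26 (−0.11 ± 0.24), Gm614 (−0.06 ± 0.18) and Flywch2 (−0.03 ± 0.32). Higher guides were 4 of 7 for Iqcd, 5 of 6 for Ttc26, 5 of 9 for Gm614 and 4 of 6 for Flywch2. The rarest tested guide stood at −2.92 for Ttc26 and at −2.31 for Flywch2. Iqcd had a rare guide at −4.70 and another at 2.09. By edgeR the genes were higher: Iqcd at 1.32, Ttc26 at 0.50, Gm614 at 0.56 and Flywch2 at 0.28. The authors' log2 fold changes were 0.076 for Iqcd, 0.42 for Ttc26, −0.039 for Gm614 and 0.46 for Flywch2. For Iqcd, 1 guide went from 7412 and 7016 normalised counts in living cells to 44153 and 55996 in dead libraries b and c, while others of its guides were lower.

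For loss, the authors' deposited table had 106 entries with a p-value under 0.05 and a lowest FDR of 0.115, that of Tmem184a, which had 2 guides and so was not in the limma fit. S100a14, a calcium-binding protein of epithelia, was placed 4 for loss in that table, and by limma it stood at −0.79 ± 0.38 with 0 of 7 guides higher. Fcho2, an early factor of endocytosis, stood at −0.37 ± 0.23 (−0.92 with the median guide and −0.0353 by edgeR) and the germ cell factor Sohlh2 at −0.23 ± 0.23. Spag17, a protein of motile cilia, stood at 0.40 ± 0.34 with 3 of 8 guides higher (−0.38 by edgeR). Across the 30 named genes, 8 had an exact binomial p under 0.05 for their guides, and 0 did after adjustment (lowest adjusted p = 0.179). All but Eola1 were chosen from these same data, so the count of 8 is partly set by that choice. Over the 915 genes in both, the limma changes and the authors' log2 fold changes had a Spearman correlation of 0.669, a value across genes, which are not replicates.

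Few genes of mitochondrial function were in this library. Of the 27 lists fixed beforehand, 19 had no tested member, no list had more than 2, and no test of a list as a whole could be run. The 9 tested genes all failed the limma test, both over all genes and adjusted over the list alone (lowest adjusted p = 0.379 over these 9). Ptcd1, a mitochondrial RNA processing factor, had the highest value, 1.00 ± 0.41, with all dead libraries above both living ones. This value rested in part on 1 of its 8 guides, which was at 0 in both living libraries. That guide had 25.9, 104 and 2.32 normalised counts in dead libraries a, b and c. Nsun4, which methylates mitochondrial ribosomal RNA, stood at 0.24 ± 0.45. Surf1, an assembly factor of cytochrome c oxidase, stood at −0.46 ± 0.33. Of the TCA cycle enzymes, Sucla2 stood at −0.14 ± 0.31 and Suclg2 at −0.06 ± 0.21. Of the sugar and lactate transporters, Slc16a1 stood at −0.61 ± 0.29 and Slc2a1 at 0.08 ± 0.28. The superoxide dismutases Sod1 and Sod2 stood at −0.27 ± 0.43 and −0.32 ± 0.60.

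Guides with no gene target gave the background of the screen. The change of a guide between living and dead cells had an SD of 1.02 log2 units for 6699 gene-targeting guides, 0.989 for 286 non-targeting guides and 1.07 for 263 safe-targeting guides. The medians were −0.09, −0.17 and 0.01. By limma on single guides, 2 gene-targeting guides passed, both lower in dead cells, and 0 of the others did. Guides of 1 gene moved together little: the intraclass correlation of their changes was 0.0109 (95% bootstrap interval −0.0022 to 0.025, permutation p = 0.0825). Taken with dead library a alone it was 0.0148 (0.0002 to 0.0299, permutation p = 0.0295), with b alone 0.0018 and with c alone 0.0059.

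**Figure D3:**
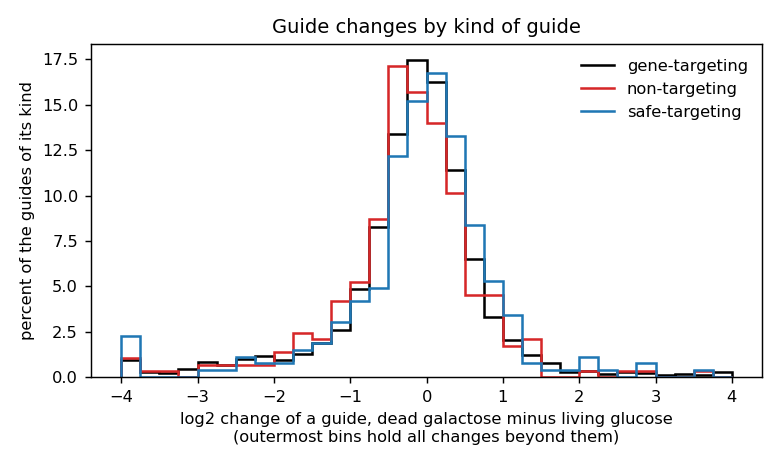
Distribution of the log2 change of single guides, dead galactose minus living glucose, as percent of the guides of each kind, in steps of 0.25, with the outermost steps holding all changes beyond them. The 3 outlines have nearly the same width, with SDs of 1.02, 0.989 and 1.07.

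The UV-RIP asked which mitochondrial RNAs were recovered with EOLA1. Most counts lay in the mitochondrial ribosomal RNAs, which took 77.4% of the 114188 counts in replicate 1 (95% Wilson interval 77.1 to 77.6) and 67.5% of the 217229 in replicate 2 (67.3 to 67.7), or 72.4% ± 7.0 (SD, n = 2). Their 51 bins make up 15.4% of the chromosome's bins. MT-RNR2, the 16S rRNA of the large ribosomal subunit, took 42.5% ± 2.06 and MT-RNR1, the 12S rRNA of the small subunit, took 30.0% ± 4.92. Per bin, MT-RNR1 stood at 5.24 ± 0.86 times the chromosome's mean and MT-RNR2 at 4.41 ± 0.21 times. With neither an input nor a control precipitation in the tables analysed, these shares do not separate binding by EOLA1 from the abundance of each RNA.

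Within the rRNAs the counts were concentrated in a few stretches. In MT-RNR1 the highest bins were 1151 to 1200, with 12063 and 15567 counts in replicates 1 and 2, and 1201 to 1250, with 7333 and 11093. In MT-RNR2 the highest bins of replicate 2 were 2101 to 2150, with 4140 and 16605 counts, and 2151 to 2200, with 2850 and 15346. Those of replicate 1 were 2251 to 2300, with 4842 and 6426 counts, and 2201 to 2250, with 4606 and 6284. Of the 10 bins with the most counts, 7 were shared by both replicates, and 9 of the 10 with the highest mean share lay in rRNA.

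The 13 mRNAs together took 20.4% and 30.7% of counts. MT-ND4, a subunit of complex I, was the highest at 8.34% ± 3.74, with 5.694% and 10.985% in the replicates. By mean share it was followed by MT-CO1 at 3.34% ± 0.81, MT-ND5 at 2.25% ± 0.57, MT-CO2 at 2.22% ± 0.10 and MT-ND2 at 2.21% ± 0.77. MT-CO3 took 1.85% ± 0.76, MT-ND1 1.62% ± 0.28, MT-ATP6 1.19% ± 0.16 and MT-CYB 0.843% ± 0.039. The others were MT-ND6 at 0.611% ± 0.139, MT-ND4L at 0.501% ± 0.072, MT-ATP8 at 0.315% ± 0.006 and MT-ND3 at 0.250% ± 0.135. Per bin MT-ND4 stood at 0.989 ± 0.444 times the chromosome's mean, and no other mRNA was above MT-CO2 at 0.566 ± 0.025. The MT-ND4 bin with the most counts over both replicates, from 12001 to 12050, had 1068 and 6600 counts, placing 26 and 6 among all bins.

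The tRNAs took 2.05% and 1.60% of counts. MT-TE had the highest mean, 0.568% ± 0.536, through its 1082 counts in replicate 1. In replicate 2 MT-TV, with 519 counts, was above MT-TE, with 411. MT-TV took 0.244% ± 0.007 and MT-TL2 at 0.145% ± 0.044. The other named tRNAs, MT-TS2, MT-TW, MT-TN, MT-TC, MT-TI, MT-TK and MT-TD, took between 0.105% and 0.052%. A tRNA is about as short as 1 or 2 bins, so its counts hold part of its neighbours'. Across all bins the replicates had a Spearman correlation of 0.939, and of 0.91 without the rRNA bins, with bins not being independent replicates.

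**Figure D4:**
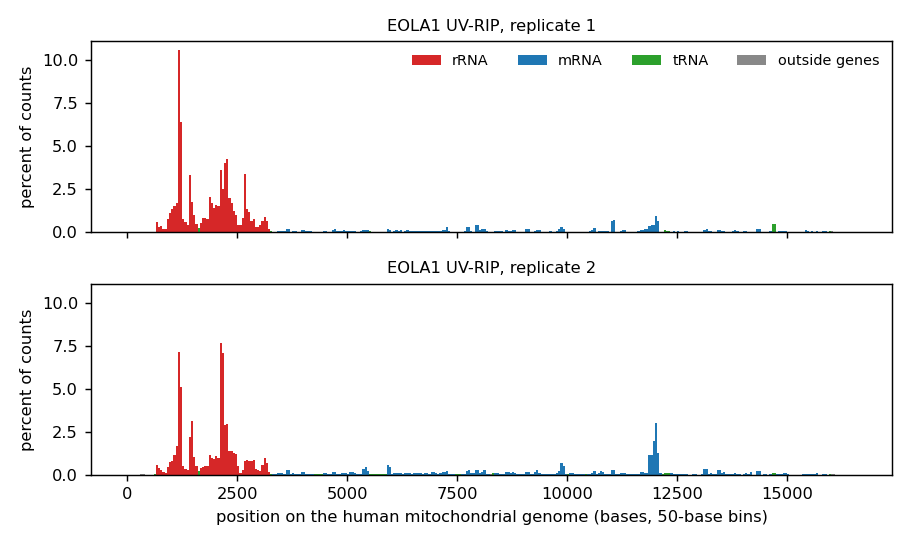
Percent of EOLA1 UV-RIP counts per 50-base bin along the human mitochondrial chromosome (position in bases) in replicates 1 and 2, coloured by the class of RNA at the bin's midpoint. The rRNA bins hold 77.4% and 67.5% of counts, and the peak outside them lies in MT-ND4.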

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

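The tests of drift, counting noise, size factors, guide abundance and pseudo-genes were chosen after the values had been seen, and that of guide agreement before. The pseudo-gene test replaced an earlier test of the same explanation, the share of lower guides among guides with no gene target, after that one had come out mixed (61.5% of non-targeting, 48.7% of safe-targeting and 56.4% of gene-targeting guides lower). The guide abundance test replaced one set before its value was seen (42.7% lower in the most abundant group), whose groups were formed with the dead libraries and so depended on the change itself. The size factor test was extended by a further centring after the first gave 64.9%. The wording of the drift explanation was also changed after its value was known. Shares with an FDR under 0.05 in the authors' guide table were taken over the guides with a mean of at least 10. They were 42.0% of 286 non-targeting guides (95% Wilson interval 36.4 to 47.7) and 46.0% of 263 safe-targeting guides (40.1 to 52.0). For gene-targeting guides the share was 43.2%. Non-targeting and safe-targeting guides stand outside the gene comparison and have no gene to lose. The non-targeting guides, entered in the authors' deposited gene table as 1 gene, were placed 9 of 925 entries for loss, with an FDR of 0.372 and a log2 fold change of −0.17. There were 3 guides at 0 in both living libraries that passed a floor set at 3 reads in all dead ones. They were against Ptcd1, 4930564B18Rik and Plk2, while 44 guides showed the opposite. The Ptcd1 guide was only at that floor in dead library c, with 2.32 normalised counts at 0.774 per read. The Ptcd1 guide contributes to the value of Ptcd1 above. In the UV-RIP, bins assigned to the mitochondrial control region, which holds no gene, had 245 and 398 counts, or 0.215% and 0.183%. Of these, 64 and 109 lay in the bin from 16001 to 16050, which reaches past the region's edge. The control region counts were noted only for being above 0, a bar that any stray read passes.

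Single guides changed widely between living and dead cells, and dead libraries b and c shared these changes, with a correlation of 0.613 over 4794 gene-targeting guides with a mean of at least 200. Library a shared less with them (0.273 and 0.295). The shared living libraries alone would give about 0.043 for b and c, and a covariance of 0.024 against the observed 0.345, so part of the excess, though a small one, comes from them. As whole causes, 2 explanations are argued against. Counting noise of the reads made up at most 9.2% of the SD of the changes in b and c. Loss of the targeted gene would make guides of 1 gene move together, if they act alike. Over all dead libraries the intraclass correlation was 0.0109 with an upper bound of 0.025. For guides with a mean of at least 200 it was 0.0035 with an upper bound of 0.0219. Drift unrelated to the gene remains open and may underlie the pattern, since guides with no gene target shared the changes of b and c as strongly (correlation of 0.659), and a common origin of b and c is not given in the sources used here.

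More genes had lower than higher guides in dead cells (68.2% lower). Pseudo-genes drawn from guides with no gene target were lower in 68.3% of cases (95% bootstrap interval 58.5 to 75.0). That argues against loss of the targeted genes as the whole cause. Those of safe-targeting guides alone gave 57.9% (44.6 to 69.5), so the pooled value rests largely on non-targeting guides (76.6%). Single gene-targeting guides were lower more often than safe-targeting ones (56.4% against 48.7%, Fisher's exact adjusted p = 0.0239). A part for loss of the targeted genes therefore stays open. Size factors remain open: 64.9% of genes were lower after centring on the median level of non-targeting guides, which moved the median gene by 0.034, but 48.1% (Wilson interval 44.9 to 51.3) after centring on their median change of −0.170. The second share follows from the median gene lying at −0.156, next to that value, so it cannot decide the question. Safe-targeting guides had a median change of 0.0056. Loss of rare guides remains open and may contribute: with guides split into 4 equal groups by 1 living library and the change taken against the other, 63.1% and 64.8% were lower in the rarest group and 48.8% and 49.9% in the most abundant one. A change of medium or of cell state is untested, since both differ between the groups.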

How the results depend on the processing

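No paired analysis was possible because the columns carry no replicate numbers. Camera on the lists fixed beforehand was not run, as no list had 5 tested members. The count of genes past the threshold was 0 in each direction under all 15 alternatives, with lowest adjusted p from 0.0549 (edgeR, added after the data were seen) to 0.9996. When 1 living library was left out the test rested on the spread of the dead ones. Eola1 kept its direction and stayed short of the threshold under 13 of 14 alternatives (0.154 to 0.357, adjusted p from 0.351 to 1.000). Leaving out each library gave 0.154, without dead library c, to 0.357, without dead library b. Without a guide filter Eola1 was at −0.17, through the added rare guide. The authors' deposited table had 0 genes for gain at any FDR tried and 1 for loss at an FDR of 0.25. Guide agreement within genes gave 0 genes with and without the filter, and the 9 added lists 0 under every setting. Among 28 other named genes, 361 of 392 values kept their direction and side, and 15 genes were never reversed. For those that were, the cause was not tested. By edgeR, Nat9 was −0.23, Tbc1d14 −0.0871, Lrwd1 0.0792, Rgs10 0.40, Sp1 −0.0717, Iqcd 1.32, Ttc26 0.50, Flywch2 0.28, Gm614 0.56 and Spag17 −0.38. At a pseudocount of 10, Iqcd was 0.0768, Ttc26 0.15 and Flywch2 0.20, and with guides of a mean of at least 50 they were 0.29, 0.45 and 0.43. With the median guide of each library, 4930564B18Rik was −0.0419, Nat9 −0.53, Atxn7l3b −0.00737, Hormad1 −0.26, Ttc26 0.55, Gm614 0.20 and Spag17 −0.14. Centred on non-targeting guides, Flywch2 was 0.00662. Leaving out each library gave −0.393 to 0.0652 for Iqcd, −0.290 to 0.0749 for Ttc26 and −0.305 to 0.117 for Flywch2. The share of UV-RIP counts in rRNA stayed between 67.5% and 77.4% and that in mRNA between 20.4% and 30.7%, ranges set by the 2 replicates. In the screen the median guide had 149 reads or more, and depth limits the rare guides.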

Other observations

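The 9 lists compiled after the gene names and leading genes had been seen gave no list past camera (lowest adjusted p = 0.494), and none with an estimated correlation (lowest adjusted p = 0.903). Genes needed by most dividing cells, such as splicing, transcription elongation and secretion factors, had lower guides for 22 of 28 members, with a mean of −0.37 ± 0.48 (SD over genes). Sec61a1 was one of them (−0.28 with guides of a mean of at least 50), as were the elongation factors Supt6 at −1.09 ± 0.27 and Supt5 at −0.71 ± 0.20, while the splicing genes Snrpe and Snrpd1 stood at 0.26 ± 0.18 and 0.25 ± 0.25. The list's fry test gave an adjusted p of 0.0870 and 0 members passed over all genes. That test sets a list against no change and not against the other genes, and 68.2% of all genes were lower. Camera, which compares a list with the other genes, gave this list an adjusted p of 0.494. SOX transcription factors were lower for 8 of 9 members (mean −0.36) and synaptic and vesicle fusion genes for 13 of 16 (mean −0.35), beside a mean of −0.18 over all genes.

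Solute carriers were lower for 12 of 18 members (mean −0.23), cilium assembly genes for 11 of 18 (mean −0.12), chromatin regulators for 9 of 17 (mean −0.05) and proteins known in mitochondria for 8 of 10 (mean −0.07). Secreted cytokines and hormones were lower for 8 of 15 members (mean −0.16). These counts are to be read beside the 68.2% of all tested genes that were lower.

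Among guides with a mean of at least 200, the 20 with the largest gain among dead cells, looked up after their values were seen, belonged to 20 different genes. The first were guides of Pih1d2 (2.78), Tex19.2 (2.72), Spag17 (2.57), Desi2 (2.46) and Nsun4 (2.35). The Nsun4 guide went from a mean of 1226 normalised counts in living cells to 3805, 15174 and 4208 in dead libraries a, b and c, and the other 14 tested Nsun4 guides had a median change of 0.19. Over the 20 genes, the median change of the other guides had a median of 0.03.

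Non-targeting guides were lower in dead cells for 176 of 286 (61.5%) and safe-targeting guides for 128 of 263 (48.7%), a difference with a Fisher's exact p of 0.00265 (adjusted p = 0.00796 over 3 comparisons among kinds of guides). Gene-targeting guides lay between, with 56.4% lower. By the same test they differed from safe-targeting guides (adjusted p = 0.0239) but did not pass against non-targeting guides (adjusted p = 0.0882). Guides are not replicate cultures, and the comparisons were made after the values were seen.

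The UV-RIP replicates differed most, among bins with over 200 counts, at MT-TE and at MT-ND6 and MT-ND4. The bin from 14701 to 14750 in MT-TE had 524 counts in replicate 1 and 180 in replicate 2. The bin from 11951 to 12000 in MT-ND4 had 445 and 4238, a share 5.01 times as high in replicate 2. The bin from 2651 to 2700 in MT-RNR2 had 3872 and 1683 counts.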
